A study of Mus musculus with 24 samples.

How the data were processed

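Per the labels, NIH3T3 cells received 1 mM DFMO for 96 h and then 10 µM spermidine with 1 mM aminoguanidine, and RNA was taken at 8 time points with 3 biological replicates each. Per the submitters' processing notes, the array scans were handled in Partek with robust multi-array averaging (RMA). The log2 scale of the deposited values is not stated there and was inferred from the values and this method. The version of the software is not given in the sources used here. The deposited values were used as they stand, without a further transformation or normalization. In these values the 3 replicate numbers have equal means over the 8 times for every gene, with a median gap of 5e-06 and a largest one of 8.75e-05. An effect of replicate number was thus removed before deposit, by a step that the sources used here do not describe.

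Of 35399 probe sets, 21789 carried 1 gene symbol, 1621 several and 11989 none. Those with 1 symbol entered the tests, and for the 999 genes with several such probe sets the one with the highest mean over the 24 arrays was taken, which gave 19938 genes. Symbols were compared with the RefSeq annotation: 0 were updated, and 91 without a match were kept as given.

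A linear model with 1 mean per time point was fitted over all 24 arrays with limma 3.58.1 in R 4.3.3, with the data.table package in version 1.17.8, with moderated, two-sided tests on 16 residual and 3.48 prior degrees of freedom. A second fit with replicate number as a block, on 14 residual degrees of freedom, accounts for the removed effect. It had been set out as an alternative before the data were seen, and its counts are given beside the others because of the equal means. The comparisons were each later time against 0 min, each pair of neighbouring times, the mean of 360, 480 and 600 min against that of 30, 60 and 120 min, and an F-test over the 7 differences from 0 min. The p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05 with no minimum change. Changes are log2 differences with the standard error of the model, and group means are given with their SD.

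Named genes were chosen by rule. Against 0 min these were the 5 largest rises and 5 largest falls among called genes whose 3 arrays all lay beyond the 3 arrays at 0 min, and for each interval and the late against early comparison the 3 largest in each direction. Gene models without a proper name were passed over. Every measured gene of polyamine metabolism was included, with up to 6 members of each other list by the F-test and up to 4 by their p at 30, 60 or 120 min. Genes named outside the rule are said to have been chosen after their values were seen.

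The 30 gene lists were drawn up from general knowledge and covered polyamine metabolism, transport and hypusine, immediate early genes, G1/S and DNA replication, G2/M and mitosis, replication-dependent histones, p53 targets, ATF4 and the amino acid response, the unfolded protein response, heat shock and chaperones and NRF2 targets. Others covered ribosome biogenesis, aminoacyl-tRNA synthetases, translation factors, nucleotide synthesis, sterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, FOXO targets, lysosome and autophagy, the proteasome, NF-kB targets, interferon-stimulated genes, extracellular matrix and matrix metalloproteases. The rest covered the response to TGF-beta and BMP, markers of macrophages, epithelium, adipocytes and muscle, and mitochondrially encoded RNAs. Some lists share members, so their tests are not independent. Examples are Btg2 (immediate early and p53), Slc3a2 (polyamine and ATF4), Sesn2 (p53 and ATF4), Slc7a11 (ATF4 and NRF2), and Cars and Nars (ATF4 and synthetases). Lists with at least 5 measured members, 29 in all, were tested at each of the 7 times against 0 min with camera at a preset correlation of 0.01, with p-values adjusted by Benjamini-Hochberg over all 203 tests. The tests were repeated with the correlation estimated for each list, and with fry, which asks whether the members of a list move on balance one way without reference to other genes. In 32 of the 203 pairs the median, mean and test did not share a sign, and none of these was called. The lists, comparisons, named-gene rule and first set of alternatives were fixed before the data were examined.

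In a test on constructed differences of 0.5, 1 and 2 on the log2 scale, those of 0.5 were recovered in 91.0% (120 min) to 97.0% (60 min) of genes. Of all genes called, over the 3 sizes together, 2.96% (30 min) to 5.83% (120 min) were false. At 600 min a shift of 0.2 gave an unadjusted p under 0.05 in 100% of 100 lists of 25 genes and no shift in 4%. The share after adjustment over 203 tests was not simulated. The constructed noise was drawn independently for each gene and array, with no correlation between genes and no removed replicate effect. These rates hold for such noise only and do not show the error rates in the deposited values.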

Results

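RNA levels were measured in NIH3T3 cells, an immortalised mouse embryonic fibroblast line, that the submitters describe as arrested by polyamine depletion and then given spermidine. The cells had been kept for 96 h in 1 mM difluoromethylornithine (DFMO), an irreversible inhibitor of ornithine decarboxylase, the enzyme that makes putrescine. Spermidine, a polyamine, was added to 10 µM together with 1 mM aminoguanidine, which blocks the amine oxidases of serum. Cells were harvested before spermidine (0 min), after 30, 60 and 120 min, and then every 120 min up to 600 min. Each of the 8 time points had 3 biological replicates, which gave 24 Affymetrix MoGene 1.0 ST arrays, each hybridised with material from 200 ng of total RNA. The question was how transcription changes with time once spermidine is given to such cells. Polyamine content and growth were not measured on the arrays. None of the 24 arrays is labelled as coming from dishes kept in DFMO without spermidine for the same times. The comparisons with 0 min therefore hold time in culture and the handling of the addition along with spermidine. The labels do not say whether the 0 min cells received aminoguanidine.

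The medians of the deposited log2 values of the 24 arrays lay between 4.40 and 4.45. The number of arrays limits the precision: the median standard error of a difference between 2 time points was 0.0567, with a median 95% confidence half-width of 0.118, both on the log2 scale. The first principal component held 63.1% of the variance over 19938 genes and ordered the time points from 30 min on, from a mean of -18.2 at 30 min to 25.1 at 600 min, with 0 min at -15.6. A pair of arrays stood apart from their labelled time. Replicate 3 labelled 120 min lay at 2.61, against -12.2 for both other 120 min arrays, and replicate 3 labelled 240 min lay at -13.2, against 2.07 and 1.49. Both were kept under the labels they carry, and the number of genes called in each comparison is also given without them, an alternative chosen after the array correlations were seen. Because these arrays were picked for lying away from their own time, leaving them out narrows the spread within times by selection. The p-values without them may thus be too small, and added calls without them are no independent support.

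Replicate numbers had left no trace of their own in the deposited values. For every gene the mean over the 8 times was the same for all 3 replicate numbers to within 8.75e-05 on the log2 scale, while numbers reassigned at random within times gave median gaps between 0.0270 and 0.0469 in 100 draws. An effect of replicate number had therefore been taken out before deposit, a step the sources used here do not describe. The fit reported here counts 16 residual degrees of freedom where 14 remained after that step, so its p-values are somewhat too small. A fit with a replicate block, which allows for the step and had a median standard error of 0.0605, is given beside it.

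**Figure D1:**
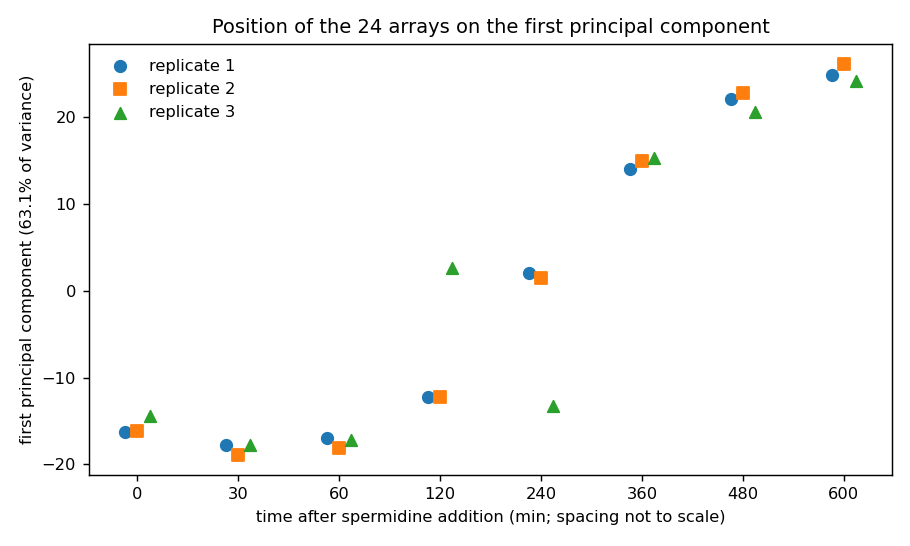
Position of each of the 24 arrays on the first principal component of 19938 genes (vertical axis, arbitrary units, 63.1% of the variance) at each time after spermidine addition (horizontal axis, minutes, not to scale), with a marker shape per replicate. Replicate 3 at 120 min (2.61) and replicate 3 at 240 min (-13.2) lie away from the other arrays of their time point.

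At 30 min, 3 genes had risen and 0 had fallen against 0 min. Egr1, a zinc finger transcription factor gene of the immediate early class, rose from 4.43 ± 0.19 to 6.46 ± 0.88 (SD, n = 3), a log2 change of 2.03 ± 0.32 (SE, limma adjusted p = 0.0358). Zfp36, which encodes an mRNA-destabilising protein, rose by 0.64 ± 0.10 (adjusted p = 0.0358), and Nppb, the gene of brain natriuretic peptide, by 0.60 ± 0.10 (adjusted p = 0.0386). Of the 34 measured immediate early genes, 2 rose over all genes tested and 15 when adjusted over the list alone. The list as a whole was higher (median log2 change 0.27, camera adjusted p = 2.88e-27). That call was kept with the correlation between members estimated (adjusted p = 0.0268 with an estimated correlation). Other members lay higher without passing the test over all genes, among them Btg2 (1.68, adjusted p = 0.140), Ier2 (1.40, 0.140), Ccn1 (1.18, 0.101), Fos (0.61, 0.140) and Jun (0.43, 0.140), which were singled out after their values were seen. The 27 p53 targets had a median of 0.16, with 0 called (3 adjusted over the list alone, camera adjusted p = 1.46e-10, and adjusted p = 0.158 with an estimated correlation). Btg2 belongs to both of these lists. Among other lists, camera called histones (median 0.14), G2/M genes (0.07) and ATF4 and the amino acid response (0.08) higher, and sterol synthesis (-0.09) lower. None of them was kept with an estimated correlation. With the replicate block limma called 0 genes at 30 min, with 827 at an unadjusted p under 0.05, against 3 called and 1104 without the block. Adjusted p was then 0.112 for Egr1 and Zfp36 and 0.122 for Nppb, while camera still called the immediate early list (adjusted p = 0.0339 with the block and an estimated correlation). The calls at 30 min rested on few arrays. By limma 0 genes were called without replicate 1, 2 or 3 of 0 min or replicate 1 or 2 of 30 min, and 7 without replicate 3 of 30 min. In the former cases Egr1, Zfp36 and Nppb had adjusted p from 0.0770 to 0.269. Leaving out the pair of arrays that stood apart gave 7 genes up and 1 down, among them all 3 named here, but 0 with the replicate block as well. Without the block Ccn1 then passed the test (adjusted p = 0.0201).

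At 60 min Egr1 was still higher (2.35 ± 0.32, adjusted p = 0.00473), joined by Ccn1, which encodes a secreted matrix protein induced by growth factors (1.41 ± 0.22, adjusted p = 0.0157). H1f5, a linker histone gene, fell by 1.29 ± 0.11 (adjusted p = 1.25e-05). The 2 other falls were Rassf1, the gene of a Ras-association domain protein (-0.56, adjusted p = 0.0157), and the microRNA gene Mir181b-1 (-0.29, adjusted p = 0.0298), chosen after its value was seen because the count was small. In all, 2 genes rose and 3 fell. The immediate early list stayed higher, with 2 of 34 members up (14 adjusted over the list alone), a median of 0.24 and a camera adjusted p of 2.18e-21 (adjusted p = 0.0356 with an estimated correlation). Of 15 replication-dependent histone genes 1 fell (8 adjusted over the list alone). The list was lower (median -0.24, camera adjusted p = 2.11e-11, and adjusted p = 0.0268 with an estimated correlation). Egr1 and H1f5 kept their calls whichever array was left out, but Ccn1 lost its call without replicate 3 of 0 min or replicate 2 or 3 of 60 min (0.0989 to 0.138). Rassf1 lost it without replicate 1 (0.0722), 2 (0.0530) or 3 (0.0910) of 0 min or replicate 3 of 60 min (0.1004), and Mir181b-1 without any of the 6 (0.0530 to 0.198). The count fell to 3 without replicate 1 or 2 of 0 min or replicate 2 of 60 min and to 2 without replicate 3 of 60 min. It was 6 up and 5 down without the pair of arrays that stood apart. With the replicate block only Egr1 and H1f5 were called, and adjusted p was 0.0501 for Ccn1 and Rassf1 and 0.108 for Mir181b-1. A fit to only the 6 arrays compared called 0 genes at 60 min, so Egr1 and H1f5 were not called there either.

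By 120 min most changed genes were lower: 9 rose and 85 fell. The core histone gene H2bc18 fell by 1.23 ± 0.16 (adjusted p = 0.00145) and H1f5 by 1.02 ± 0.11 (adjusted p = 6.06e-04). Trappc5, of a vesicle-tethering complex, fell by 0.96 and Gadd45g, a stress-inducible growth-arrest gene, by 0.97. So did Atf4, the transcription factor gene of the integrated stress response, by 0.94 ± 0.17 (adjusted p = 0.0133). Txnip (-0.92), the gene of a thioredoxin-binding protein, Ier5 (-0.85), an immediate early gene, and Plk2 (-0.67), a p53-inducible kinase gene, also fell. The largest rises were Cdc25a, which encodes a phosphatase that activates cyclin-dependent kinases (0.53 ± 0.12, adjusted p = 0.0475), and the Polycomb gene Cbx2 (0.45 ± 0.09, adjusted p = 0.0180). The histone list was lower (2 of 15 fell and 6 adjusted over the list alone, median -0.27, camera adjusted p = 8.34e-09, and adjusted p = 0.0480 with an estimated correlation, a call lost at 0.0554 with the replicate block as well). The immediate early list, higher at 60 min, now had a median of -0.15, with 1 of 34 lower (2 up and 6 down adjusted over the list alone). Its camera call (adjusted p = 0.0294, and adjusted p = 0.605 with an estimated correlation) ended without replicate 2 of 0 min (0.145) or replicate 2 of 120 min (0.119). The 45 genes of the G1/S transition and DNA replication had a median of 0.23 with 1 member higher (1 adjusted over the list alone, camera adjusted p = 4.31e-11, and adjusted p = 0.395 with an estimated correlation). Without the pair of arrays that stood apart that median was 0.02 (adjusted p = 0.313), and without replicate 3 of 120 min alone the adjusted p was 0.449.

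The 120 min count depended on single arrays. It was 13 without replicate 1 and 57 without replicate 2 of 0 min, and 50, 234 and 20 without replicates 1, 2 and 3 of 120 min. H2bc18, H1f5, Rassf1 and Trappc5 kept their calls whichever of these arrays was left out, while all 13 other named genes called at 120 min lost theirs without replicate 1 of 0 min, Atf4 (0.0929), Txnip (0.0749), Gadd45g (0.0885), Ier5 (0.0885), Plk2 (0.0974), Cdc25a (0.215) and Cbx2 (0.141) among them. Those 7 also lost it without replicate 3 of 120 min, with adjusted p of 0.0719, 0.0527, 0.0719, 0.0687, 0.0656, 0.238 and 0.0904 in the same order. Cdc25a lost it too without replicate 2 (0.121) or 3 (0.0767) of 0 min, Atf4 without replicate 2 of 0 min (0.0504), Gadd45g without replicate 3 of 0 min (0.0558) and Cbx2 without replicate 1 of 120 min (0.0733). Without the pair of arrays that stood apart 2 genes rose and 45 fell, 38 of them shared with the 94, Atf4 was at -0.68 (adjusted p = 7.98e-05) and Cbx2 was no longer called (adjusted p = 0.0605). Once the replicate block was fitted 1 gene, Cbx2, rose and 39 fell, and Cdc25a had an adjusted p of 0.107.

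At 240 min, 73 genes were higher and 537 lower than at 0 min. H2bc18 fell by 1.38 ± 0.16 and Trappc5 by 1.13 ± 0.13 (adjusted p = 1.87e-04 for both). Atf4 (-1.05 ± 0.17, adjusted p = 0.00188), Txnip (-1.07 ± 0.15, 5.67e-04), Ier5 (-0.97 ± 0.14, 9.23e-04), Plk2 (-0.89 ± 0.12, 3.79e-04) and H1f5 (-0.95 ± 0.11, 2.17e-04) were lower as well, and none of these 7 calls ended when any 1 array was left out. Nppb, higher at 30 min, was now lower (-0.59, adjusted p = 0.00221). The largest rises were the chemokine gene Cxcl5 (1.06 ± 0.25, adjusted p = 0.0262), the sterol genes Hmgcs1 (0.79) and Insig1 (0.74), the carbonyl reductase gene Cbr3 (0.76) and the glycolytic gene Pfkl (0.74). All 5 of these calls ended without replicate 1 of 0 min (adjusted p from 0.114 to 0.215), replicate 2 of 0 min (0.0630 to 0.0947) or replicate 1 or 2 of 240 min (0.0936 to 0.225). Those of Cxcl5, Cbr3 and Pfkl ended without replicate 3 of 0 min (0.0509 to 0.0908). Fitting the replicate block lost those of Cxcl5 (0.0528), Hmgcs1 (0.0553), Cbr3 (0.0879) and Pfkl (0.0650) and kept that of Insig1, and 30 genes rose and 326 fell. Cdc6, which licenses replication origins, was at 0.82 (adjusted p = 0.158) and was not called.

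By list, 6 of 27 p53 targets fell at 240 min (1 up and 12 down adjusted over the list alone, median -0.24, camera adjusted p = 3.68e-08, and adjusted p = 0.207 with an estimated correlation). Of 37 genes of ATF4 and the amino acid response 5 fell (9 adjusted over the list alone, median -0.19, camera adjusted p = 2.96e-08, and adjusted p = 0.395 with an estimated correlation). So did 6 of 43 ribosome biogenesis genes (15 adjusted over the list alone, median -0.12, camera adjusted p = 2.23e-08, and adjusted p = 0.221 with an estimated correlation). Of 21 targets of NRF2, the oxidative stress transcription factor, 4 rose (7 adjusted over the list alone, median 0.14, camera adjusted p = 2.02e-07, and adjusted p = 0.178 with an estimated correlation). In the G1/S list 1 of 45 rose (1 adjusted over the list alone, median 0.29, camera adjusted p = 1.04e-09, and adjusted p = 0.449 with an estimated correlation). With the pair of arrays that stood apart left out, 24 G1/S genes were higher and the list was called with an estimated correlation too (adjusted p = 0.00735). The total then rose to 492 up and 1171 down, with 583 of the 610 genes shared. It was 212 and 338 without replicates 1 and 2 of 0 min, and 200, 205 and 1298 without replicates 1, 2 and 3 of 240 min.

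From 360 min on, many more genes differed from 0 min. The counts were 1689 up and 2103 down at 360 min, 1940 and 2894 at 480 min, and 2236 and 3134 at 600 min. Changes of at least 1 on the log2 scale leaned the other way, with 86 up and 55 down at 360 min, 140 and 79 at 480 min, and 191 and 100 at 600 min. At 360 min the largest rises were Cdc6 (2.59 ± 0.30, adjusted p = 1.02e-05), Chaf1b, of the assembly factor that loads histones onto new DNA (2.25 ± 0.25, 8.15e-06), Cxcl5 (2.04), Hmgcs1 (1.96) and the replication licensing regulator Dtl (1.92). The largest falls were the linker histone gene H1f2 (-2.15 ± 0.27, adjusted p = 1.69e-05), the costimulatory gene Cd80 (-2.13), Eda2r, a p53-induced receptor gene (-1.82), Btbd19 (-1.76) and Stk40 (-1.53). At 600 min the sterol genes Idi1 (3.29 ± 0.23, adjusted p = 2.62e-09) and Nsdhl (3.28 ± 0.11, 1.26e-13) led, a 9.76-fold and a 9.69-fold rise, followed by Ranbp3l (3.00), Mvd (2.87) and Lss (2.79). H1f2 (-2.28), Cd80 (-2.05), the clock repressor gene Nr1d1 (-1.73), Ddit3, a stress-induced transcription factor gene (-1.72), and Chchd5 (-1.65) fell furthest. At 480 min the same rule named Idi1 (2.79), Nsdhl (2.57), Chaf1b (2.53), Hmgcs1 (2.48) and Ranbp3l (2.42) as rising, and H1f2 (-2.51), Cd80 (-1.95), Btbd19 (-1.80), Tcta (-1.75) and the activin antagonist gene Fst (-1.71) as falling. Without the pair of arrays that stood apart the counts were 1870 and 2238, 2073 and 3042, and 2395 and 3287. They were 1452 and 1815, 1691 and 2653, and 1961 and 2863 with the replicate block, and every gene named here kept its call. None of the genes named here at 360, 480 or 600 min lost its call when any 1 array was left out. All comparisons with 0 min share its 3 arrays and are not independent of each other.

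**Figure D2:**
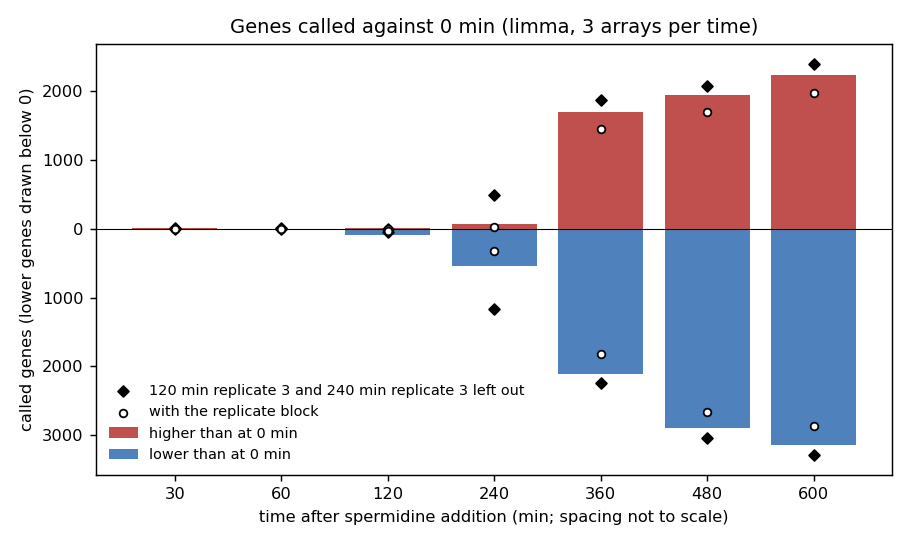
Number of genes called higher (bars above 0) or lower (bars below 0) than at 0 min by limma (vertical axis) at each time after spermidine addition (horizontal axis, minutes, not to scale), 3 arrays per time point. Diamonds give the counts without 120 min replicate 3 and 240 min replicate 3, which move most at 240 min, from 73 up and 537 down to 492 and 1171. White circles give the counts with the replicate block, 30 and 326 at 240 min.

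Genes of the G1/S transition and DNA replication formed the most uniform rise at 360 min. Of 45 members 42 rose and 1 fell (43 and 1 adjusted over the list alone), with a median of 1.05. The median was still 1.03 at 480 min and 1.04 at 600 min, when 41 were higher and 1 was lower (43 and 1 adjusted over the list alone). At 600 min the rises included Tk1, thymidine kinase (2.12 ± 0.14), the replicative helicase subunit gene Mcm7 (1.73 ± 0.16) and Pcna, the polymerase clamp (1.48 ± 0.14). Ccne1, cyclin E1, had risen by 1.46 at 360 min, while Ccnd1, cyclin D1, was the member that fell (-0.55 at 360 min and -0.53 at 600 min); both were singled out after their values were seen. Camera adjusted p was 2.03e-34 at 360 min and 1.06e-27 at 600 min (adjusted p = 0.113 and 0.137 with an estimated correlation). Without the pair of arrays that stood apart the values with an estimated correlation were 9.25e-04 and 0.00129. Across all lists and times, 7 of 100 groupings of the 24 arrays, the real one counted, gave at least as many called list tests as the 81 found. With times exchanged only within replicate numbers and the replicate block in the fit, 5 of 100 did, the real one counted. This concerns the number of list calls and does not test the G1/S list by itself. The regrouped arrays also still held the differences between times. Genes of G2/M and mitosis rose later, 11 of 37 at 360 min, 21 at 480 min and 26 at 600 min (12, 24 and 28 adjusted over the list alone), and 1, 1 and 0 fell at these times. Aurkb (1.21 ± 0.11) and Bub1 (1.05 ± 0.10), of the mitotic checkpoint, and cyclin A2, Ccna2 (0.94 ± 0.10), were among those higher at 600 min. The median of that list went from 0.14 to 0.48 (camera adjusted p = 4.09e-13 at 600 min, and adjusted p = 0.207 with an estimated correlation).

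Replication-dependent histone genes did not follow the G1/S genes upward at 360 min. Of 15 measured members 0 rose and 7 fell (10 adjusted over the list alone), with a median of -0.38 (camera adjusted p = 5.04e-06, and adjusted p = 0.113 with an estimated correlation). H1f2 (-2.15 ± 0.27), H1f3 (-0.60 ± 0.10) and H1f5 (-0.62 ± 0.11) were lower. By 600 min the members had parted: 5 were higher and 4 lower (5 and 4 adjusted over the list alone), with a median of 0.08 and no call for the list (camera adjusted p = 0.649). H1f5 was then higher (1.09 ± 0.11, adjusted p = 5.18e-07), as was H4c6 (0.67 ± 0.17), while H1f2 (-2.28) and H1f3 (-0.42) stayed lower.

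Sterol synthesis genes, which make the enzymes of the cholesterol pathway and its regulators, rose furthest. At 240 min 2 of 20 were higher (6 adjusted over the list alone), at 360 min 16 (18 adjusted over the list alone), and at 480 and 600 min all 20 (20 adjusted over the list alone); 0 fell at any of these times. The median change was 0.23 at 240 min, 1.13 at 360 min, 1.91 at 480 min and 2.28 at 600 min. Hmgcs1, hydroxymethylglutaryl-CoA synthase, was at 2.73 ± 0.19 at 600 min, Mvd, mevalonate diphosphate decarboxylase, at 2.87 ± 0.16, and Lss, lanosterol synthase, at 2.79 ± 0.12 (adjusted p = 4.03e-12). Camera adjusted p was 5.04e-34 at 480 min and 3.10e-35 at 600 min (adjusted p = 0.0268 and 0.0268 with an estimated correlation). At 360 min it was 2.67e-24 (adjusted p = 0.0577 with an estimated correlation), and at 240 min 1.36e-05 (0.449 with an estimated correlation).

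Targets of p53 were mostly lower at 360 min: 17 of 27 fell and 2 rose (20 and 2 adjusted over the list alone), with a median of -0.62. At 600 min 17 fell and 1 rose (19 and 1 adjusted over the list alone), with a median of -0.39. At 600 min Eda2r (-1.49), Plk2 (-1.15), Aen, a p53-induced nuclease gene (-1.13 ± 0.11), and Mdm2, the p53 ubiquitin ligase (-1.05 ± 0.16), were lower. Sesn1, a p53 and FOXO target, was the member that rose (2.20 ± 0.21). Camera adjusted p was 1.90e-09 at 360 min and 2.14e-06 at 600 min (adjusted p = 0.164 and 0.301 with an estimated correlation).

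Genes of ATF4 and the amino acid response fell throughout the late times, 25 of 37 at 360 min, 30 at 480 min and 32 at 600 min (28, 31 and 32 adjusted over the list alone), against 0, 1 and 0 that rose (1, 2 and 1 adjusted over the list alone). At 600 min Atf4 stood at -1.33 ± 0.17, Ddit3 at -1.72 ± 0.16, Trib3, a pseudokinase gene, at -1.52 ± 0.22, and Slc7a5, an amino acid transporter gene, at -1.56 ± 0.10. The list median moved from -0.42 to -0.74 (camera adjusted p = 9.15e-17 at 600 min, and adjusted p = 0.160 with an estimated correlation). Of the 18 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, 12 fell and 0 rose at 600 min (13 and 0 adjusted over the list alone), among them Yars (-1.10 ± 0.11) and Lars (-0.87 ± 0.08). As drawn up, this list shares genes such as Cars and Nars with the ATF4 list, so the falls are not separate results. Their median was -0.52 (camera adjusted p = 1.62e-09, and adjusted p = 0.153 with an estimated correlation).

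Ribosome biogenesis genes were lower as well, 22 of 43 at 360 min, 27 at 480 min and 33 at 600 min, and 0 rose (24, 27 and 36 lower, and 2, 0 and 0 higher, adjusted over the list alone). Rrp12, of small-subunit export, was at -1.22 ± 0.11 at 600 min, Nob1, the endonuclease that trims 18S rRNA, at -0.81 ± 0.07, and Noc3l at -0.74 ± 0.08. The list median at 600 min was -0.36 (camera adjusted p = 1.74e-17, and adjusted p = 0.0925 with an estimated correlation, or 0.00831 without the pair of arrays that stood apart). Translation initiation and elongation factors moved less: 9 of 24 fell and 2 rose at 600 min (11 and 3 adjusted over the list alone), with Eif2s2 at -0.86 ± 0.06. Their median was -0.07 (camera adjusted p = 0.00573, and adjusted p = 0.221 with an estimated correlation).

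Of 22 genes of the unfolded protein response of the endoplasmic reticulum 17 were higher at 360 min and 12 at 600 min, with 0 lower (18 and 12 higher, and 0 and 1 lower, adjusted over the list alone). Manf, a secreted stress-response protein gene, stood at 0.70 ± 0.13 and Calr, the chaperone calreticulin, at 0.66 ± 0.10 at 600 min. The median went from 0.50 to 0.32 (camera adjusted p = 4.98e-05 at 600 min, and adjusted p = 0.501 with an estimated correlation). Of 20 cytosolic heat shock and chaperone genes 15 rose and 1 fell at 600 min (15 and 1 adjusted over the list alone), among them Hsph1 (1.11 ± 0.13) and Bag3 (0.94 ± 0.16). They had a median of 0.33 (camera adjusted p = 1.57e-06, and adjusted p = 0.113 with an estimated correlation). NRF2 targets were higher in 15 of 21 cases at 360 min (16 adjusted over the list alone) and in 10 at 600 min (13 adjusted over the list alone), and lower in 1 and 2 (1 and 2 adjusted over the list alone). Nqo1, a quinone reductase gene, rose by 2.34 ± 0.26 and Gclm, of glutathione synthesis, by 1.04 ± 0.16 by 600 min, whereas the heme oxygenase gene Hmox1 was lower (-0.81 ± 0.16). Camera adjusted p for that list was 4.94e-10 at 360 min and 1.32e-05 at 600 min (adjusted p = 0.127 and 0.280 with an estimated correlation). Of 23 glycolysis and hypoxia genes 16 rose and 2 fell at 600 min (18 and 2 adjusted over the list alone), with Pfkl and the mitophagy gene Bnip3 both at 2.57 and Pdk1 at 1.95. That median was 0.48 (camera adjusted p = 1.72e-10, and adjusted p = 0.0917 with an estimated correlation). Proteasome genes moved little, with 10 of 28 higher and 1 lower (11 and 3 adjusted over the list alone), Psmd1 at 0.69, and a median of 0.14 (camera adjusted p = 0.00106, and adjusted p = 0.506 with an estimated correlation).

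**Figure D3:**
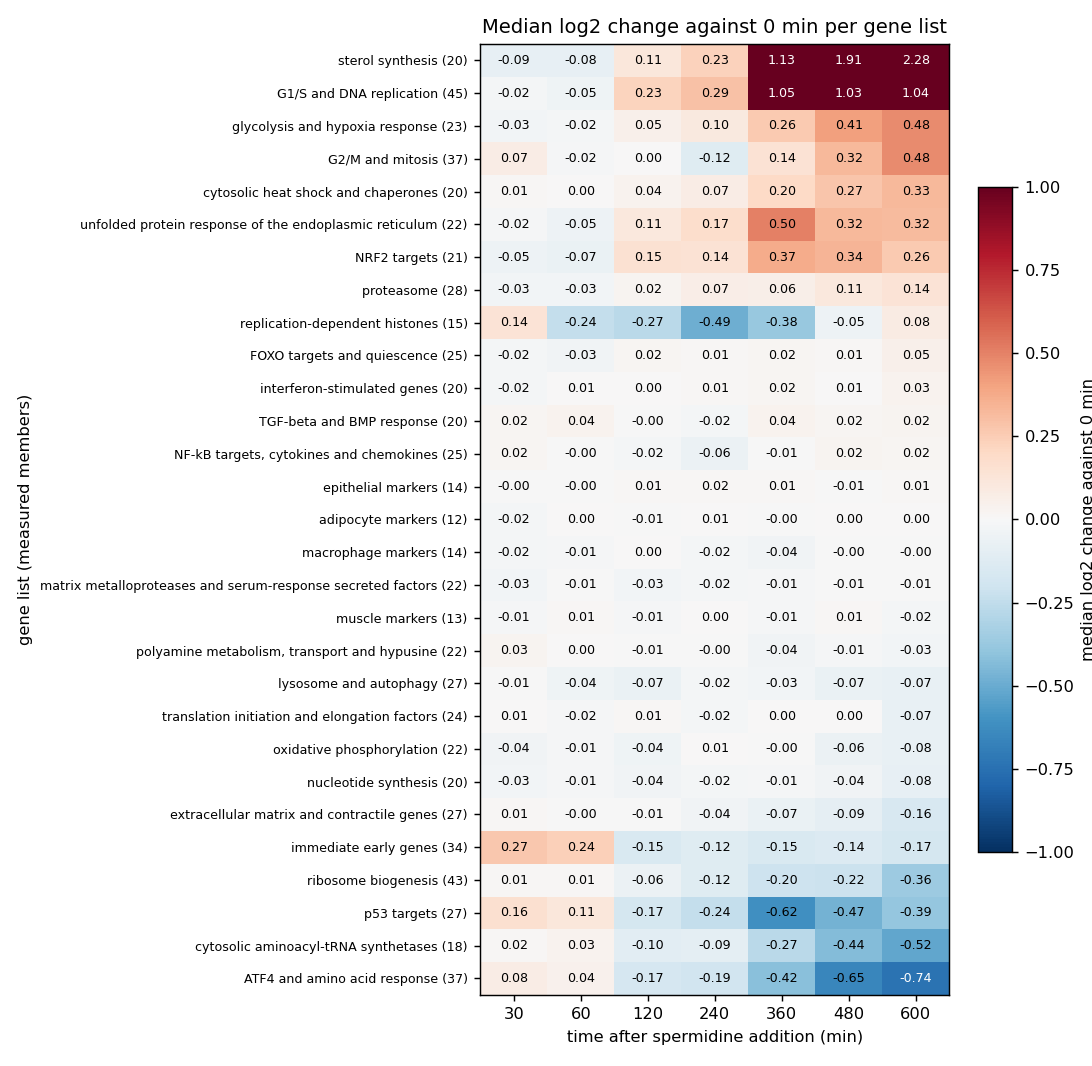
Median log2 change against 0 min (colour and printed value) of 29 gene lists (vertical axis, with the number of measured members) at each time after spermidine addition (horizontal axis, minutes), over 3 arrays per time point. Sterol synthesis reaches 2.28 and ATF4 and the amino acid response -0.74 at 600 min, while the lists of other cell types stay near 0.

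Genes of polyamine metabolism, transport and hypusine synthesis went both ways. Of 22 measured members 0 were called at 30, 60 and 120 min (0, 0 and 1 lower adjusted over the list alone). At 240 min 1 was lower, Slc3a2 (-0.31, 3 lower adjusted over the list alone), which lost its call without replicate 1 of 0 min (0.0758) or replicate 1 of 240 min (0.0643). At 600 min 4 rose and 8 fell (4 and 8 adjusted over the list alone). Oaz2, an antizyme that drives degradation of ornithine decarboxylase, rose by 1.23 ± 0.16 (adjusted p = 6.36e-06). Sat1, the acetyltransferase that starts spermidine catabolism (0.69 ± 0.07), Smox, spermine oxidase (0.71 ± 0.10), and Oat, ornithine aminotransferase (0.41 ± 0.09), were also higher. Odc1, ornithine decarboxylase itself, fell by 0.44 ± 0.07 (adjusted p = 4.69e-05). Also lower were Azin1 (-0.36) and Azin2 (-0.48), the antizyme inhibitors, Srm, spermidine synthase (-0.34), Dhps, deoxyhypusine synthase (-0.48), Slc3a2 (-0.74), and the transporter genes Atp13a3 (-0.69) and Atp13a2 (-0.26). The list median was -0.03, and the list was called at no time (camera adjusted p = 0.459 at 600 min).

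**Figure D4:**
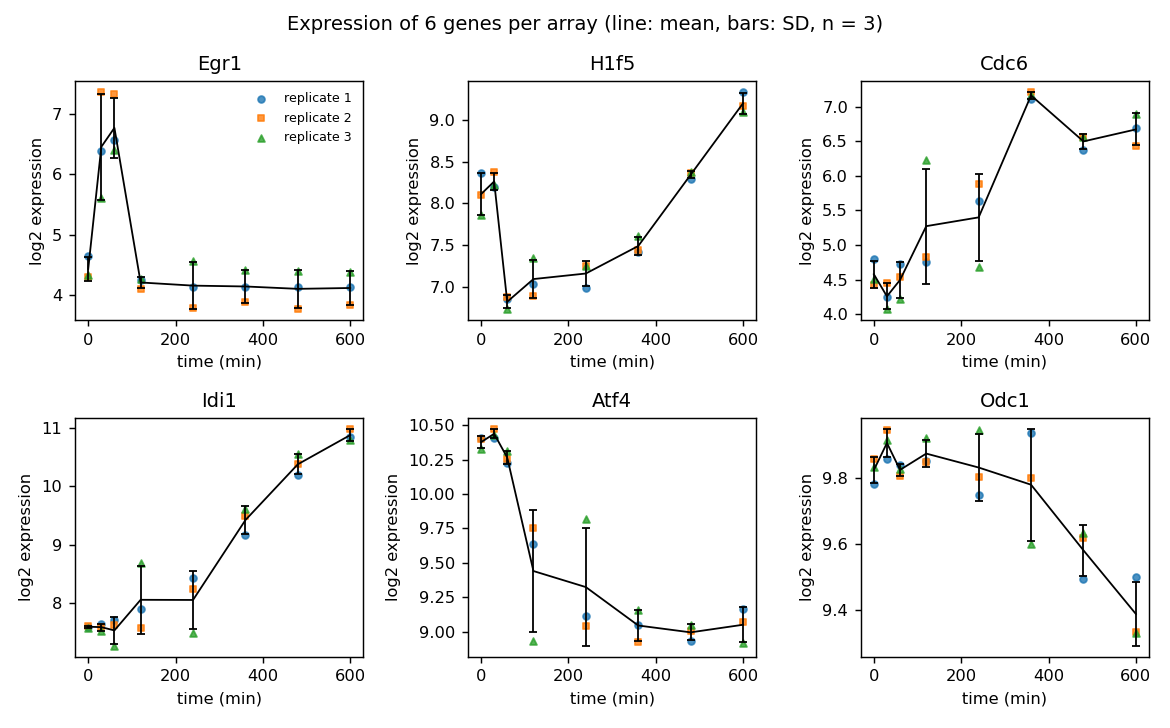
Log2 expression (vertical axes, a separate range per gene) of Egr1, H1f5, Cdc6, Idi1, Atf4 and Odc1 against time after spermidine addition (horizontal axes, minutes), with a marker per array, lines through the means and bars of 1 SD (n = 3). Egr1 rises by 30 min, H1f5 is lowest at 60 min and above its 0 min level at 600 min, and at 120 and 240 min replicate 3 lies away from the other replicates for Cdc6, Idi1 and Atf4.

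Other lists moved little as wholes by 600 min. Extracellular matrix and contractile genes fell in 13 of 27 cases and rose in 2 (16 and 2 adjusted over the list alone), with Myl9 at -1.17, Col5a2 at -0.88 and Tgfbi at 1.19. They had a median of -0.16 (camera adjusted p = 0.00200, and adjusted p = 0.320 with an estimated correlation). Of 22 oxidative phosphorylation genes 6 fell and 1 rose (6 and 1 adjusted over the list alone), with a median of -0.08 (camera adjusted p = 0.0266, and adjusted p = 0.522 with an estimated correlation), a call that ended without replicate 2 of 600 min (0.0539). Among 25 FOXO target and quiescence genes 10 rose, such as Sesn1 and Pdgfra (1.37), and 4 fell, such as Txnip (-1.04), 11 and 4 adjusted over the list alone. That list had a camera adjusted p of 0.0458 (adjusted p = 0.356 with an estimated correlation) and lost its call without replicate 2 (0.0511) or 3 (0.0564) of 0 min or replicate 1 (0.0959) or 2 (0.0531) of 600 min. No call was made at 600 min for nucleotide synthesis (4 of 20 up and 5 down, 4 and 6 adjusted over the list alone, median -0.08), lysosome and autophagy (2 of 27 up and 6 down, 2 and 6 adjusted over the list alone, median -0.07) or NF-kB targets (3 of 25 up and 2 down, 3 and 2 adjusted over the list alone), although the chemokine genes Cxcl5 (2.36) and Ccl2 (1.10) rose. The same held for interferon-stimulated genes (2 of 20 up, 1 adjusted over the list alone), matrix metalloproteases and secreted factors (3 of 22 up and 5 down, 3 and 5 adjusted over the list alone) and the response to TGF-beta and BMP (4 of 20 up and 3 down, 4 and 3 adjusted over the list alone).

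Markers of other cell types stayed near their 0 min levels. At 600 min the medians were 0.00 for 12 adipocyte, 0.01 for 14 epithelial, -0.02 for 13 muscle and -0.00 for 14 macrophage markers. Camera called none of these lists at any time, and adjusted p at 600 min ran from 0.846 to 0.978. Adipocyte markers had 0 calls at 600 min, macrophage markers 1 rise (Tyrobp, 0.13), epithelial markers 1 rise (Krt14, 0.36) and 1 fall (Cdh1, -0.29), and muscle markers 2 falls (Acta1, -0.33, and Des, -0.27). Adjusted over the list alone, 0, 0, 1 and 1 members passed. COX2, the 1 measured transcript of the mitochondrial genome, used as a sign of RNA quality, was higher by 0.13 ± 0.05 at 600 min. The calls of Tyrobp (0.0578), Krt14 (0.0684), Acta1 (0.0503) and COX2 (0.0586) were lost with the replicate block. Each of these calls but that of Cdh1 rested on single arrays. Acta1 lost its call without replicate 1 or 3 of 0 min or any 600 min array (0.0509 to 0.137), Tyrobp without replicate 1 or 3 of 0 min or replicate 2 or 3 of 600 min (0.0799 to 0.125), and COX2 without replicate 2 or 3 of 0 min or replicate 1 or 3 of 600 min (0.0648 to 0.157). Des lost it without replicate 3 of 0 min (0.0620) or replicate 1 of 600 min (0.123), and Krt14 without replicate 3 of 0 min (0.290) or replicate 2 (0.149) or 3 (0.132) of 600 min.

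Neighbouring times were also compared directly. From 30 to 60 min 2 genes rose and 7 fell, among them H1f5 (-1.44 ± 0.11, adjusted p = 1.83e-06), H2bc14 (-1.08) and H2bc18 (-0.96), while Set, the gene of a histone chaperone, rose (0.30). From 60 to 120 min 21 rose and 61 fell: Egr1 (-2.57 ± 0.32, adjusted p = 4.07e-04), Ccn1 (-2.27) and Btg2 (-2.09) dropped back, and Cdc25a (0.88), Mylip (0.75) and Cbx8 (0.57) rose. From 30 to 60 min the count was 3 and 1 without replicates 1 and 2 of 30 min and 1, 3 and 1 without replicates 1, 2 and 3 of 60 min, 6 without replicate 3 of 30 min. H1f5 alone of the 4 named genes kept its call each time (others 0.0575 to 0.230). From 60 to 120 min it was 35 and 37 without replicates 2 and 3 of 60 min and 199 and 27 without replicates 2 and 3 of 120 min. Mylip (0.106) and Cbx8 (0.0733) lost their calls without replicate 3 of 120 min, as Mylip did without replicate 3 of 60 min (0.0908). When the pair of arrays that stood apart was left out, 2 rose and 10 fell from 30 to 60 min, and 5 rose and 45 fell from 60 to 120 min. Only H1f5 was called with the replicate block from 30 to 60 min (0.0693 for H2bc14, H2bc18 and Set), and 5 rose and 32 fell from 60 to 120 min.

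From 120 to 240 min limma called 0 genes, with 1879 at an unadjusted p under 0.05 and 1 gene called with an intensity trend and a robust prior. Over this interval 1413 genes had all 3 arrays at 240 min above all 3 at 120 min and 1066 below, where chance alone separates 10% of genes. Without replicate 2 of 120 min 1 gene was called, and without replicate 3 of both times 225 rose and 299 fell. With the replicate block limma called 0 genes as well, with 1405 at an unadjusted p under 0.05. From 240 to 360 min 848 genes rose and 359 fell. Cdc6 (1.76 ± 0.30, adjusted p = 0.00201), Chaf1b (adjusted p = 0.00194) and Brca1, of homologous recombination (1.42), led the rises, and H1f2 (-1.35), Eda2r (-1.20) and Cd80 (adjusted p = 0.0209) the falls. That count was 280 without replicate 3 of 240 min, 712 and 489 without replicates 2 and 3 of 360 min, 455 up and 148 down without the pair of arrays that stood apart, and 576 up and 200 down with the replicate block. H1f2 (0.0545) and Cd80 (0.156) lost their calls without replicate 3 of 240 min, and Cd80 also without replicate 1 (0.0780) or 2 (0.0604) of 360 min.

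Later intervals held fewer changes. From 360 to 480 min 58 genes rose and 64 fell, led by the sterol genes Mvd (1.21 ± 0.16, adjusted p = 0.00112), Nsdhl (1.20) and Lss (1.09) upward and Hmox1 (-0.71), Slc7a5 (-0.56) and Zfr (-0.52) downward. From 480 to 600 min 30 rose and 6 fell. Pmvk, phosphomevalonate kinase (0.93 ± 0.13, adjusted p = 0.00176), H1f5 (0.85) and the sterol reductase gene Tm7sf2 (0.78) rose most, and Car6 (-0.35), Slc12a9 (-0.34) and Pkia (-0.30) fell. The 360 to 480 min count was 42 and 61 without replicates 1 and 2 of 360 min and 77, 77 and 62 without replicates 1, 2 and 3 of 480 min. Hmox1 was not called when any 1 of the 6 arrays was left out (0.0573 to 0.155). The 480 to 600 min count was 23 and 18 without replicates 1 and 2 of 480 min. Slc12a9 lost its call without replicate 1, 2 or 3 of 480 min or replicate 2 or 3 of 600 min (0.0846 to 0.206), and Car6 without replicate 2 or 3 of 480 min or replicate 3 of 600 min (0.0597 to 0.0818). The 360 to 480 min split of 58 up and 64 down turned to 67 and 40 with a repeated quantile normalization, 55 and 39 with an intensity trend and a robust prior, and 51 and 33 with only the arrays compared. The counts without the pair of arrays that stood apart were 110 and 127 from 360 to 480 min and 68 and 23 from 480 to 600 min. Those with the replicate block were 36 and 29, and 17 and 4, and Hmox1 (0.0853) and Slc12a9 (0.101) lost their calls.

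The direct contrast of the late times (360, 480 and 600 min) with the early ones (30, 60 and 120 min), which uses no 0 min array, called 3272 genes higher and 3867 lower late. Ranbp3l (2.63 ± 0.19, adjusted p = 1.28e-09), Idi1 (adjusted p = 1.73e-11) and Nsdhl (2.46 ± 0.06, 7.89e-16) rose most. H1f2 (-2.18 ± 0.15, adjusted p = 8.13e-10), Cd80 (-1.86) and Eda2r (-1.64) fell most, and none of these 6 calls ended when any 1 array was left out. The count without the pair of arrays that stood apart was 3256 up and 3880 down, and with the replicate block 2975 and 3666. Over the whole course, the F-test across the 7 comparisons with 0 min called 6166 genes, or 5351 with the replicate block and 6310 without the pair of arrays that stood apart. Of the 203 pairs of a list and a time tested, 81 were called with the preset correlation and 6 with an estimated one, or 81 and 5 with the replicate block. Without the pair of arrays that stood apart, 74 were called with the preset correlation and 36 with an estimated one. The loss under an estimated correlation thus varied with this pair. Since the pair was picked for its deviation in these same values, the added calls do not show that the lists changed.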

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

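The split between 120 and 240 min, all tests on the placement of the arrays, the Myc test, both histone tests and the regroupings within replicate numbers were chosen after the results were seen, while the other splits and the test of a trend with expression level were set out before.

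Replicate 3 labelled 120 min and replicate 3 labelled 240 min each lay nearer the other time point. Their correlation with the other arrays of that time exceeded that with their own by 0.00141 in both cases, with the pair left out of the time means. For the other 22 arrays the best-matching time exceeded the own one by at most 0.00055, with the pair kept in the means. With the pair kept, replicate 3 of 240 min correlated best with 0 min (0.99803), ahead of 60 min (0.99797) and 120 min (0.99791). A lag or lead of the whole culture set 3, which would move both arrays the same way, is argued against. Taken relative to 0 min, which cancels the offset removed before deposit, replicate 3 deviated on the first component by -16.8 at 240 min but by 13.0 at 120 min, and by at most 3.66 at the other 5 times. Poor hybridization cannot be told apart from the other causes. The gaps of up to 0.00141 are what singled the arrays out, and the best correlation with any array was 0.99808 for replicate 3 of 240 min but 0.99793 for replicate 3 of 120 min, below the 0.99804 to 0.99883 of the other 22, which keeps this open. An exchange of the labels of these arrays may explain the pattern, as a hypothesis drawn from the same correlations, and dishes collected away from their stated time stay open and untested.

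Ribosome biogenesis genes were lower at 600 min, with a list median of -0.36. A trend with expression level left by the normalization is argued against as the whole cause, since 10000 lists matched for expression had a median of -0.09 (the middle 95% from -0.21 to 0.02), the difference was -0.28 and 0% of them lay as low. Whether a lower level of Myc, an activator of these genes, came first cannot be told apart from the reverse order. Its transcript was called lower only at 480 min (-0.56) and 600 min (-0.62, limma adjusted p = 0.00136). Before that it was uncalled at 0.28, 0.36, -0.48, -0.40 and -0.34 in order of time (adjusted p from 0.0925 to 0.898), while the list was called lower from 120 min on (camera adjusted p = 0.0168, and adjusted p = 0.608 with an estimated correlation). That call ended without replicate 2 of 0 min (0.137) or replicate 3 of 120 min (0.238). Without the pair of arrays Myc was called lower at 120 min (-0.70, adjusted p = 0.00298) and the list was not (adjusted p = 0.126). The order thus turned on the doubted arrays, which keeps it open, and Myc protein was not measured.

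The histone list was called higher at 30 min by camera (median 0.14), a call not kept with an estimated correlation. Histone transcripts then fell by 60 min and several rose between 240 and 600 min. A single signal shared by all histone probe sets is argued against, since H1f2 changed by -1.49 from 240 to 600 min while 8 others rose, among them H1f5 (2.04), H2ac4 (1.36) and H4c6 (1.22). H2bc21 was the other member that fell (-0.28, adjusted p = 0.0355), and sharing between close pairs such as H4c4 and H4c6 stays open. Entry into S phase is a candidate explanation for the rise. From 240 to 600 min the whole histone list had a median of 0.18 (camera p = 1.25e-04, or 0.0276 with an estimated correlation), and the G1/S list one of 0.85 (p = 3.64e-28, or 0.0145 with an estimated correlation). The interval was picked after the rise had been seen, which makes these p-values too small, and DNA synthesis was not measured.

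The 10 splits of 3 arrays against 3 cannot give a share under 0.05. In every comparison of this kind but that of 120 with 240 min, 1 split, the real one, gave as many genes. The real and highest other counts were 3 and 0 at 30 min, 5 and 0 at 60 min, 94 and 1 at 120 min, 610 and 5 at 240 min, 3792 and 1 at 360 min, 4834 and 0 at 480 min, and 5370 and 1 at 600 min. For the intervals they were 9 and 1 (30 to 60 min), 82 and 0 (60 to 120 min), 1207 and 0 (240 to 360 min), 122 and 0 (360 to 480 min) and 36 and 2 (480 to 600 min). Between 120 and 240 min the real count was 0, which all 10 splits reach, so this comparison says nothing about chance. The split that put replicate 3 of 240 min with replicates 1 and 2 of 120 min gave 1200, which restates the placement of these arrays and points to a structure of the samples. Of 100 regroupings, 1, the real one, reached the 6166 genes of the F-test (highest other 3388) and 1 the 7139 of the late against early comparison (highest other 4718). A random order of the arrays is argued against for both, as far as 100 draws show. These draws ignored the replicate effect removed before deposit. For the list tests 7 of 100, the real one counted, gave at least the 81 called pairs (highest other 101), so chance was not excluded for their number. With times exchanged only within replicate numbers and the replicate block in the fit, 1 of 100 reached the 5351 genes of the F-test (highest other 4), 1 the 6641 of the late against early comparison (highest other 836) and 5 the 81 list tests (highest other 97). The real grouping is counted in each of these. The regrouped arrays still carried their differences between times. The shares for the list tests therefore do not show how often 81 calls would come without such differences, and chance is neither shown nor excluded for their number.

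Some genes were called in opposite directions at different times. They were picked by those calls, so the differences below are values only and no further evidence. Ccn1 went from 1.41 at 60 min to -1.35 at 360 min, a difference of -2.76, H1f5 from -1.29 at 60 min to 1.09 at 600 min (2.37), Hmox1 from 0.63 at 240 min to -0.81 at 600 min (-1.43) and Nppb from 0.60 at 30 min to -0.59 at 240 min (-1.18). Between 360 and 600 min the differences were 1.18 for H2bc14, 0.67 for Arntl, -0.39 for Zc3h13, 0.38 for Ccl9 and -0.31 for Nup153. Between 120 and 600 min they were 0.93 for H2ac15, 0.92 for H4c14, -0.73 for Taf4b and 0.57 for Dvl2, and between 240 and 600 min 0.63 for Srsf3, 0.61 for Kif23 and 0.49 for Myd88. Nudt11 differed by -0.25 between 240 and 360 min and Olfr118 by -0.20 between 480 and 600 min. With the replicate block only H1f5, Arntl, Zc3h13, Ccl9, Nup153, H2ac15 and Nudt11 of these 18 kept both limma calls at the times given, and Srsf3 kept those at 360 and 600 min.

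Gene lists called in opposite directions by camera were picked in the same way, and their median differences are values only. They were -0.56 for immediate early genes from 30 to 360 min, 0.61 for G2/M genes from 240 to 600 min, -0.67 for histones from 30 to 240 min, -0.85 for p53 targets from 30 to 360 min, -0.85 for ATF4 and the amino acid response from 30 to 600 min, 0.43 for NRF2 targets from 60 to 360 min and 2.35 for sterol synthesis from 30 to 600 min. The call of immediate early genes at 360 min ended without replicate 2 of 0 min (adjusted p = 0.0791) or replicate 2 (0.0696) or 3 (0.0866) of 360 min, and that of G2/M genes at 240 min without replicate 1 of 0 min (0.615) or replicate 3 of 240 min (0.372). That of NRF2 targets at 60 min ended without replicate 2 (0.0818) or 3 (0.243) of 0 min or replicate 2 of 60 min (0.109), and that of sterol synthesis at 30 min without replicate 1 of 0 min (0.104) or replicate 3 of 30 min (0.112). With an estimated correlation only immediate early genes at 30 min and sterol synthesis at 600 min of these 14 calls were kept, and p53 targets at 30 min had an adjusted p of 0.158.

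Probe sets without exactly 1 symbol entered no comparison above. Of these 13610, limma called 799 at 600 min against 0 min, 368 higher and 431 lower.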

How the results depend on the processing

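The fit without replicate 3 of 120 min and replicate 3 of 240 min was chosen after seeing the data, as were the replicate block without them and the replicate block with an estimated correlation, and the other alternatives before. Of 718 calls on 238 named genes and of 81 called list tests, 0 changed the direction of the gene or of the camera or fry test under any alternative. The median, as opposed to the test, crossed 0 in 4 called lists: sterol synthesis and the unfolded protein response at 120 min without replicate 3 of 120 min, ATF4 and the amino acid response at 60 min without replicate 2 of 0 min, and the response to TGF-beta and BMP at 60 min without replicate 3 of 0 min. Among the 718 calls, 7 were lost with arrays centred on their median, 13 with a repeated quantile normalization and 13 with an intensity trend and robust prior. Array weights lost 4, the mean of all probe sets of a gene 4, only the arrays compared 103, and leaving out the pair of arrays that stood apart 10. A minimum log2 change of 1 lost 487, the replicate block 59, and the block without the pair 29. Joint adjustment over the comparisons with 0 min, and separately over the intervals, lost 29 of the 712 outside the late against early comparison. A random replicate effect (consensus correlation -0.133) moved nothing and tests nothing, since the replicate means had been made equal. With dim genes left out, those in the lowest 40% by mean signal (under 4.10), all 716 calls that could be tested were kept. Of the 81 list tests, 6 kept their call with the correlation estimated, namely immediate early genes at 30 and 60 min, histones at 60 and 120 min and sterol synthesis at 480 and 600 min, 49 with fry, 72 without the pair of arrays, 81 with the replicate block, 5 with the block and an estimated correlation (histones at 120 min were lost, 0.0554) and 72 with the block and without the pair, while 8 were lost with dim genes left out, 4 with array weights and 3 with a repeated quantile normalization. Without the pair of arrays, 36 of all 203 list tests were called with an estimated correlation. Leaving out single arrays ended the call in 459 of 4380 pairs of a gene call and a left-out array, and in 48 of 486 such pairs for lists. Each call enters these pairs once per array left out, so they are not shares of calls. Against 0 min the named calls lost without at least 1 array were 3 of 3, 3 of 5, 13 of 17 and 35 of 49 at 30, 60, 120 and 240 min. They were 32 of 185, 21 of 204 and 22 of 221 at 360, 480 and 600 min. The 8 lost with dim genes left out included translation factors (0.0789) and oxidative phosphorylation (0.232) at 600 min and extracellular matrix at 480 min (0.125). Counts at 360, 480 and 600 min stayed within 1.5 times the reported ones under every alternative but the minimum change of 1. So did the late against early count, which was in neither joint adjustment, and the count over the course, which was also not run with a minimum change or only the arrays compared.

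Counts that moved were as follows, and unless the alternative itself shows it the cause was not tested. Array weights gave 13 genes at 30 min, 1283 at 240 min, 207 from 360 to 480 min and 56 from 480 to 600 min. Leaving out dim genes gave 5 at 30 min and 153 at 120 min, and the intensity trend with a robust prior gave 1 from 120 to 240 min. With only the arrays compared, which leaves fewer arrays to estimate the spread, the counts were 0 at 60 min, 6 at 120 min, 32 at 240 min, 4 from 30 to 60 min, 5 from 60 to 120 min, 177 from 240 to 360 min and 18 from 480 to 600 min. A minimum log2 change of 1, which can only remove genes, left 1 gene at 30 min, 3 at 60 min, 2 at 120 min, 12 at 240 min, 141 at 360 min, 219 at 480 min and 291 at 600 min. Over the intervals and late against early it left 2 from 30 to 60 min, 13 from 60 to 120 min, 32 from 240 to 360 min, 3 from 360 to 480 min, 0 from 480 to 600 min and 173 late against early. A joint adjustment was made over the 7 comparisons with 0 min and, separately, over the 6 intervals. Within each set it lends comparisons with few calls the threshold of those with many. The counts were then 137 (66 up and 71 down), 129 (71 and 58), 565 (124 and 441) and 1036 (188 and 848) at 30, 60, 120 and 240 min. For the intervals they were 22 from 30 to 60 min, 27 from 120 to 240 min, 478 from 240 to 360 min and 69 from 480 to 600 min. Without the pair of arrays that stood apart the counts were 8, 11, 47 and 1663 at 30, 60, 120 and 240 min, 50 from 60 to 120 min, 524 from 120 to 240 min, 603 from 240 to 360 min, 237 from 360 to 480 min and 91 from 480 to 600 min.

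Whether replicate numbers pair the arrays across times cannot be read from the deposited values. The median correlation of deviations between arrays of the same number was -0.16 (-0.57 to 0.22), 7 of 84 pairs exceeded 0.1 and 0 arrays were nearest one of their own number, but equal replicate means alone leave about -0.143 for the same number and 0.0714 for different ones. With the replicate block, counts were 0, 2, 40 and 356 at 30, 60, 120 and 240 min, 1 from 30 to 60 min, 37 from 60 to 120 min, 776 from 240 to 360 min, 65 from 360 to 480 min and 21 from 480 to 600 min. They were 0, 19 and 1314 at 30, 120 and 240 min with the block and without the pair, and 35 from 60 to 120 min, 287 from 120 to 240 min and 412 from 240 to 360 min, with 5 list tests called with the block and an estimated correlation.

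Leaving out each array of a comparison in turn gave 0 to 7 genes at 30 min, 2 to 7 at 60 min, 13 to 234 at 120 min, 200 to 1298 at 240 min, 3026 to 3210 at 360 min, 4033 to 4314 at 480 min and 4556 to 5153 at 600 min. The lowest were without replicate 1 of 0 min at 30, 120 and 360 min, replicate 3 of 60 min, replicate 1 of 240 min, replicate 2 of 480 min, and replicate 2 of 0 min at 600 min, and the highest at 120 and 240 min without replicate 2 of 120 min and replicate 3 of 240 min. For the intervals the ranges were 1 to 6, 27 to 199, 0 to 1, 280 to 1422, 42 to 90 and 18 to 47 in order of time, with 6740 to 7117 late against early, 5746 to 6217 over the course and 76 to 83 called list tests.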

Other observations

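These lists were drawn up after the data were seen and are given as values and counts with no test of the list. Of 16 genes of fatty acid synthesis 9 rose and 1 fell at 360 min, 10 rose and 1 fell at 480 min and 11 rose and 0 fell at 600 min, with medians of 0.24, 0.61 and 0.95. At 600 min the desaturase gene Scd2 was at 2.21, fatty acid synthase, Fasn, at 1.98, the elongase gene Elovl6 at 1.90, Acss2 at 1.69 and ATP citrate lyase, Acly, at 1.62. Of 17 measured genes of DNA repair in S phase 12 rose at 360 and 480 min and 14 at 600 min, and 0 fell, with medians of 0.60, 0.69 and 0.74. Brca1 was at 1.68, the exonuclease gene Exo1 at 1.58 and the helicase gene Blm at 0.61 at 600 min.

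Of 17 circadian clock genes 0 rose and 5 fell at 360 min, 1 rose and 5 fell at 480 min, and 2 rose and 6 fell at 600 min, with a median of -0.08 at 600 min. The repressor genes Nr1d1 (-1.73) and Nr1d2 (-0.62) and the output gene Dbp (-0.49) were lower at 600 min, and Bhlhe40 (0.73) and Arntl (0.35) higher.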
